A study of Mus musculus with 6 samples.

How the data were processed

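Gene expression was measured by paired-end, poly(A)-selected RNA sequencing in 3 libraries labelled Sirpa-WT and 3 labelled Sirpa-KO. Per the file headers, the authors made the deposited counts, which are raw fragments per gene, with featureCounts 1.5.1 over exons of the Ensembl release 75 GTF for GRCm38. The submitters' processing notes name STAR 2.6.0 and Subread. The library kit was stranded, but the counting command carried no strand option, so overlapping genes on opposite strands were not told apart. The same form of command stands in all 6 files, and no value was normalized before deposit. Whether the file of Sirpa-KO replicate 1 came from another sample or another alignment was not settled, which bears on its values and on the trend built on them. Single-cell libraries of the same study were not analysed here.

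Groups and replicate numbers came from the sample titles. The files hold 39179 genes, of which 37607 were given a symbol from GENCODE mouse release 21 by gene identifier. Coordinates are those in the files. Total counts ranged from 338824 to 411695 in 5 libraries, where a floor of 3 counts equals 7.29 to 8.85 CPM, and reached 29877270 in Sirpa-KO replicate 1. Pairs of the shallow replicates within a group differed by more than sampling noise (chi-square per degree of freedom 1.15 to 1.45), so none was treated as a library deposited a second time. This does not show that they were separate cultures. The exact interval for the Sirpa ratio and the floors cover counting error only.

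The test, its settings, 30 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were filtered with filterByExpr (minimum count 10, about 28.0 CPM in the shallow libraries), scaled by TMM and tested with edgeR's quasi-likelihood method (glmQLFit with robust=TRUE), 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Gene lists with at least 5 tested members, 16 in all, were tested with limma camera at a correlation of 0.01, 2-sided, on log2 CPM with a prior count of 2; camera with an estimated correlation and fry were alternatives. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes under the count filter, Sirpa among them, were given values from a fit without it.

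The named genes were Sirpa, the 12 largest rises and 12 largest falls among called genes of at least 5 CPM whose groups did not overlap and whose symbol was not a predicted gene, clone or pseudogene, up to 4 called members of each list or else its most abundant member, and Cd47, Ptpn6, Ptpn11, Cd274, B2m, H2-K1, H2-D1, Mitf, Tyr and Pmel. As no gene was called over 6 libraries, the rule was applied to the planned fit without Sirpa-KO replicate 1, a choice made after the values were seen. It gave 72 genes, of which 1 is not reported here. Other list members in the text were chosen after their values were seen.

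Alternatives fixed in advance were other scalings (RLE, upper quartile, library size alone), other filters, DESeq2, limma voom, robust=FALSE, glmTreat, the replicate number as a block, and leaving out each library. Chosen after seeing the data were restriction to protein-coding genes, or to those with under 5% of their 25-base words shared with annotated pseudogenes, removal of a gene length trend, thinning of Sirpa-KO replicate 1 to the depth of the others, and removal of a trend on the ratio of that library to the mean of the other 5. The last fitted in each library a lowess curve (span 0.3) of log2 CPM, minus the gene's mean, on the log2 ratio. These curves were offsets in the 5-library fit. Clustering along chromosomes was tested by permuting genes within chromosomes.

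The tests were tried on simulated data with 200 changed genes and the dispersion of the 5 shallow libraries, not the larger one of the 6-library fit. With 6 libraries they recovered 41.8%, 88.1% and 90.9% of genes changed 1.5-, 2- and 4-fold, with 10 false among 157 calls. With 5 they recovered 20.9%, 53.7% and 89.4%, with 6 false among 115 calls.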

Results

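Poly(A)-selected RNA was sequenced from cultured B16-F10 cells, a mouse melanoma line of C57BL/6 origin, that carried either an intact Sirpa gene (labelled Sirpa-WT, 3 libraries) or a knockout of it (labelled Sirpa-KO, 3 libraries). Sirpa encodes SIRPα, a transmembrane receptor for CD47. The comparison addresses how steady-state expression differs between these tumour lines. One label field names the cell line differently and gives its source as tumour, while the series text describes B16-F10 cells in culture. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries.

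The libraries differed widely in depth. Total counts were 411695, 343808 and 345543 in Sirpa-WT replicates 1 to 3, and 29877270, 338824 and 367667 in the libraries labelled Sirpa-KO replicates 1 to 3. Sirpa-KO replicate 1, called the deep library here, thus held 82.6 times the mean of the 5 shallow libraries. In a shallow library 1 count equals 2.43 to 2.95 CPM, the unit in which each library is scaled to the same total. Processed pseudogenes, which are intronless copies of genes, took 29.0% ± 0.61 of counts in Sirpa-WT (SD, n = 3) and 26.6% ± 0.11 in the 2 shallow Sirpa-KO libraries (SD, n = 2). The share in the deep library was 0.177%. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.919 to 0.944 among the shallow libraries and 0.022 to 0.097 between any of them and the deep library. Over 3461 protein-coding genes that share little sequence with pseudogenes, r was 0.877 to 0.919 among the shallow libraries. The deep library then had r = 0.432 to 0.458 with the Sirpa-WT libraries and 0.582 and 0.584 with Sirpa-KO replicates 2 and 3. Summed CPM of 20 listed melanocyte genes was 19716 in the deep library and 14913 to 22114 in the others.

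**Figure D1:**
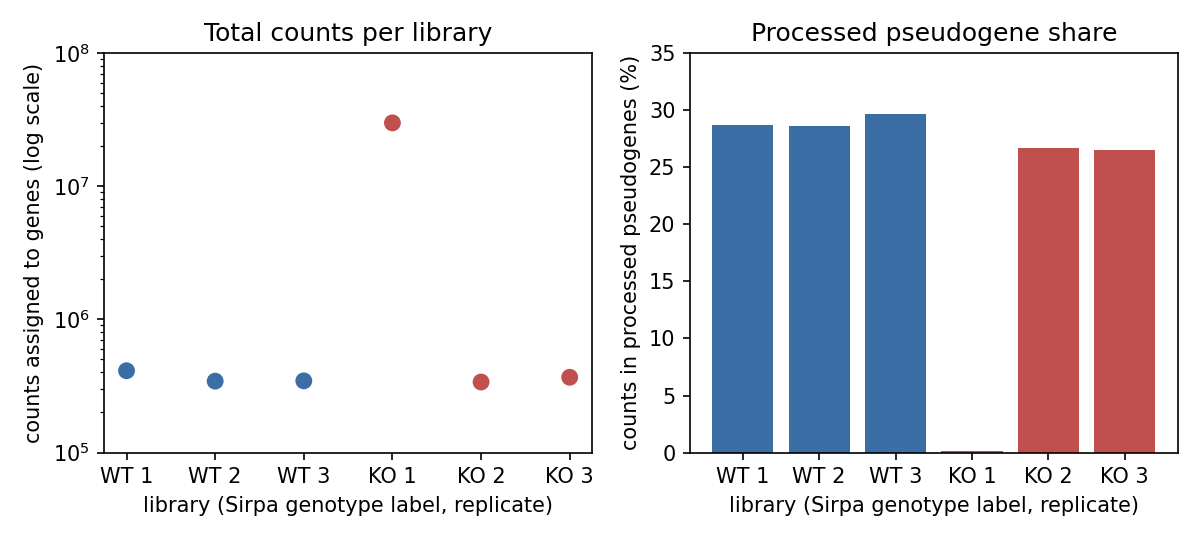
Left, total counts assigned to genes in each of the 6 libraries (log axis). Right, the percentage of those counts in processed pseudogenes; blue marks Sirpa-WT and red Sirpa-KO labels. The deep library stands at 29877270 counts and 0.177%, and the other 5 at 338824 to 411695 counts and 26.5% to 29.7%.

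Protein-coding genes that share little sequence with pseudogenes also fell into 2 sets. Of 3461 such genes, 1099 (31.8%) had a log2 ratio of the deep library to the mean of the shallow ones more than 1 below the median of 0.93; these are called low-ratio genes. The median of 0.93 over all 3461 means that CPM in the deep library is shifted upward for these 3461 as a whole, while the low-ratio genes lie below that level. They lay beside each other on the chromosomes. Neighbouring genes correlated in membership with r = 0.331 over 3439 pairs, above each of the permutations within chromosomes, whose highest value was 0.0688 (permutation p = 0.001, 1-sided, the smallest they can give). Within the shallow libraries, the same genes stood higher in Sirpa-WT, by 0.25, 0.13 and 0.11 log2 units relative to the other genes, and lower in Sirpa-KO replicates 2 and 3, by -0.26 and -0.28. The comparison of genotypes is therefore given with and without this trend.

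Sirpa RNA was not detectably lower in the libraries labelled Sirpa-KO. The gene (ENSMUSG00000037902, GRCm38 chromosome 2, 129592835 to 129632228, plus strand, 10 merged exons) had 12, 7 and 3 counts in Sirpa-WT and 1584, 6 and 6 in Sirpa-KO. That is 19.4 ± 10.3 CPM in Sirpa-WT (SD, n = 3) and 29.0 ± 20.8 in Sirpa-KO (SD, n = 3). Over the shallow libraries the Sirpa-KO to Sirpa-WT ratio was 0.85, with an exact 95% interval of 0.383 to 1.79 for counting error only and a 2-sided exact binomial p of 0.727. In edgeR's quasi-likelihood test without the count filter, which Sirpa did not pass, its log2 fold change was 0.17 ± 0.62 (SE, adjusted p = 0.938) over 6 libraries and -0.38 ± 0.53 (adjusted p = 0.806) without the deep library. Counts per gene need not fall with an edit that disrupts the protein, and the labels do not describe the edit. Sirpa counts therefore do not check the genotype labels, and directions below refer to libraries as labelled.

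Cxcl10, an interferon-induced chemokine that recruits T cells, was higher in each of the 3 libraries labelled Sirpa-KO (516 to 760 CPM) than in any Sirpa-WT library (206 to 226 CPM). Dct, which encodes the melanin-synthesis enzyme dopachrome tautomerase, lay at 2496 to 4863 CPM in Sirpa-KO and 7901 to 9935 in Sirpa-WT. With all 6 libraries, as designed, edgeR's quasi-likelihood test called none of 5397 genes (smallest adjusted p = 0.574), and the biological coefficient of variation was 75.8%. At an unadjusted p of 0.05, 344 genes passed, 254 higher and 90 lower, where chance gives 270. DESeq2 called 1 gene, Cxcl10 (log2 fold change 1.18, adjusted p = 0.0133). Limma voom called 1283 genes, 17 higher and 1266 lower.

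Without the deep library, a comparison planned as leaving out 1 replicate, 5 of 15 pigment-cell genes and 4 of 18 sterol and fatty acid synthesis genes fell in the libraries labelled Sirpa-KO, and 2 of 10 type I interferon response genes rose. Camera called these 3 lists, but each had adjusted p = 0.184 with an estimated correlation. EdgeR called 322 of 5510 genes, 73 higher and 249 lower, with a biological coefficient of variation of 7.25%. Of the calls, 210 were protein-coding genes (67 higher, 143 lower), 104 were pseudogenes (6 higher, 98 lower) and 60 exceeded a 2-fold change, although glmTreat against that bound called 0 (edgeR, same 5 libraries). Of the 156 called protein-coding genes that share little sequence with pseudogenes, 97 of 107 that fell were low-ratio genes, and 47 of 49 that rose were not. With the trend on the ratio to the deep library removed, 109 genes were called, 41 higher and 68 lower, and 83 of them were among the 322. The count was 132 with DESeq2 (all among the 322), 125 without Sirpa-KO replicate 2, 127 without Sirpa-KO replicate 3 and 214 without Sirpa-WT replicate 2. The 2-fold count was 28 and 39 without Sirpa-KO replicates 2 and 3, 9 with DESeq2 and 24 with the trend removed. Scaling by library size alone shifted the median log2 fold change from 0.013 to 0.15 and called 279 genes higher and 128 lower, so directions are relative to the bulk of genes under TMM scaling.

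Some melanocyte genes fell in the shallow libraries labelled Sirpa-KO. Of 15 measured, 5 fell, none rose and 10 did not pass edgeR's test; 8 fell when adjusted over the list alone. Dct (ENSMUSG00000022129) went from 8828 ± 1029 CPM (SD, n = 3) to 4719 ± 204 (SD, n = 2), a log2 fold change of -1.02 ± 0.08 (SE, edgeR adjusted p = 6.34e-32). Mitf, the master transcription factor of the lineage, fell from 624 ± 27.1 to 400 ± 39.1 CPM (-0.76 ± 0.13). The melanosomal ion exchanger Slc24a5 (-0.77), the trafficking GTPase Rab38 (-0.63) and the melanosome matrix protein gene Pmel (-0.48) also fell. Tyr (-0.15), Tyrp1 (-0.16) and Mlana (-0.036), which encode other pigment-cell proteins, did not pass. Removing the trend left all 5 called and added Rab27a, with Dct at -0.74 and Mitf at -0.66. Of the 15 members, 5 were low-ratio genes, and these included 4 of the 5 that fell (Dct, Mitf, Slc24a5 and Rab38). In the deep library those 4 genes stood below each Sirpa-WT library, while Pmel stood at 1221 CPM, above each of them (861 to 1049). That CPM is not corrected for the upward shift of the deep library, against which Pmel deviated downward. Camera called the list lower (adjusted p = 0.00296), but the call ended at adjusted p = 0.184 with an estimated correlation.

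Some sterol and fatty acid synthesis genes fell as well. Of 18 measured, 4 fell, none rose and 14 did not pass edgeR's test; 7 fell when adjusted over the list alone. Among those that fell were Nsdhl (-1.46 ± 0.25, SE) and Cyp51 (-1.23 ± 0.27), both enzymes of late cholesterol synthesis, and Insig1 (-1.20 ± 0.32), a sterol-regulated brake on the pathway. In CPM, Nsdhl fell from 150 ± 28.8 (SD, n = 3) to 59.8 ± 11.5 (SD, n = 2). With the trend removed 4 members were called, Nsdhl, Cyp51, Insig1 and Scd2, and 3 members were low-ratio genes, Nsdhl among them. In the deep library Nsdhl (36.1 CPM) stood below each Sirpa-WT library, while Cyp51 (147 CPM) and Insig1 (91.4 CPM) stood above each. These CPM are not corrected for the upward shift of the deep library, against which Cyp51 and Insig1 deviated downward. Nsdhl, Cyp51 and Insig1 were not called with DESeq2. Calls from fits that leave 1 shallow Sirpa-KO library are not listed in this paragraph. Over the alternatives Cyp51 ran from -1.60 to -0.95 and Insig1 from -1.34 to -1.07. The list was lower by camera (adjusted p = 5.27e-05), a call that ended at adjusted p = 0.184 with an estimated correlation.

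Some interferon-induced genes rose. Of 10 measured genes of the type I interferon response, 2 rose, none fell and 8 did not pass edgeR's test, with the same 2 when adjusted over the list alone. Isg15, a ubiquitin-like modifier, went from 71.0 ± 3.8 CPM (SD, n = 3) to 145 ± 12.4 (SD, n = 2), a log2 fold change of 0.90 ± 0.24 (SE). Ddx58, which encodes the RNA sensor RIG-I, rose by 0.60 ± 0.16. Oas1a (1.24), Ifi27 (1.20) and Rsad2 (1.18) did not pass. Cxcl10, the 1 measured member of the interferon-gamma-induced list, rose from 217 ± 9.7 to 528 ± 15.6 CPM (1.16 ± 0.15, edgeR adjusted p = 1.1e-11). With the trend removed all 3 were still called, at 1.07, 0.76 and 0.96. The trend lowers genes with a low ratio in the shallow Sirpa-KO libraries, and Isg15 and Ddx58 have such ratios. Removing it therefore raised their values, which adds no support for their rise. Isg15 and Ddx58 were not called with DESeq2, nor was Ddx58 without Sirpa-WT replicate 2. Leaving out Sirpa-KO replicate 2 or 3 leaves 1 shallow Sirpa-KO library, so calls from those fits are not listed in this paragraph. Over the alternatives Isg15 ran from 0.79 to 1.07 and Ddx58 from 0.45 to 0.77. Isg15 (66.9 CPM) and Ddx58 (175 CPM) were not raised in the deep library, and Isg15 shares 15.4% of its sequence words with pseudogenes. Camera called the type I list higher (adjusted p = 0.00126), and adjusted p = 0.184 with an estimated correlation. Of the 10 members, 3 had a ratio under the same bound, among them Isg15, which lies outside the 3461 genes, and Ddx58.

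**Figure D2:**
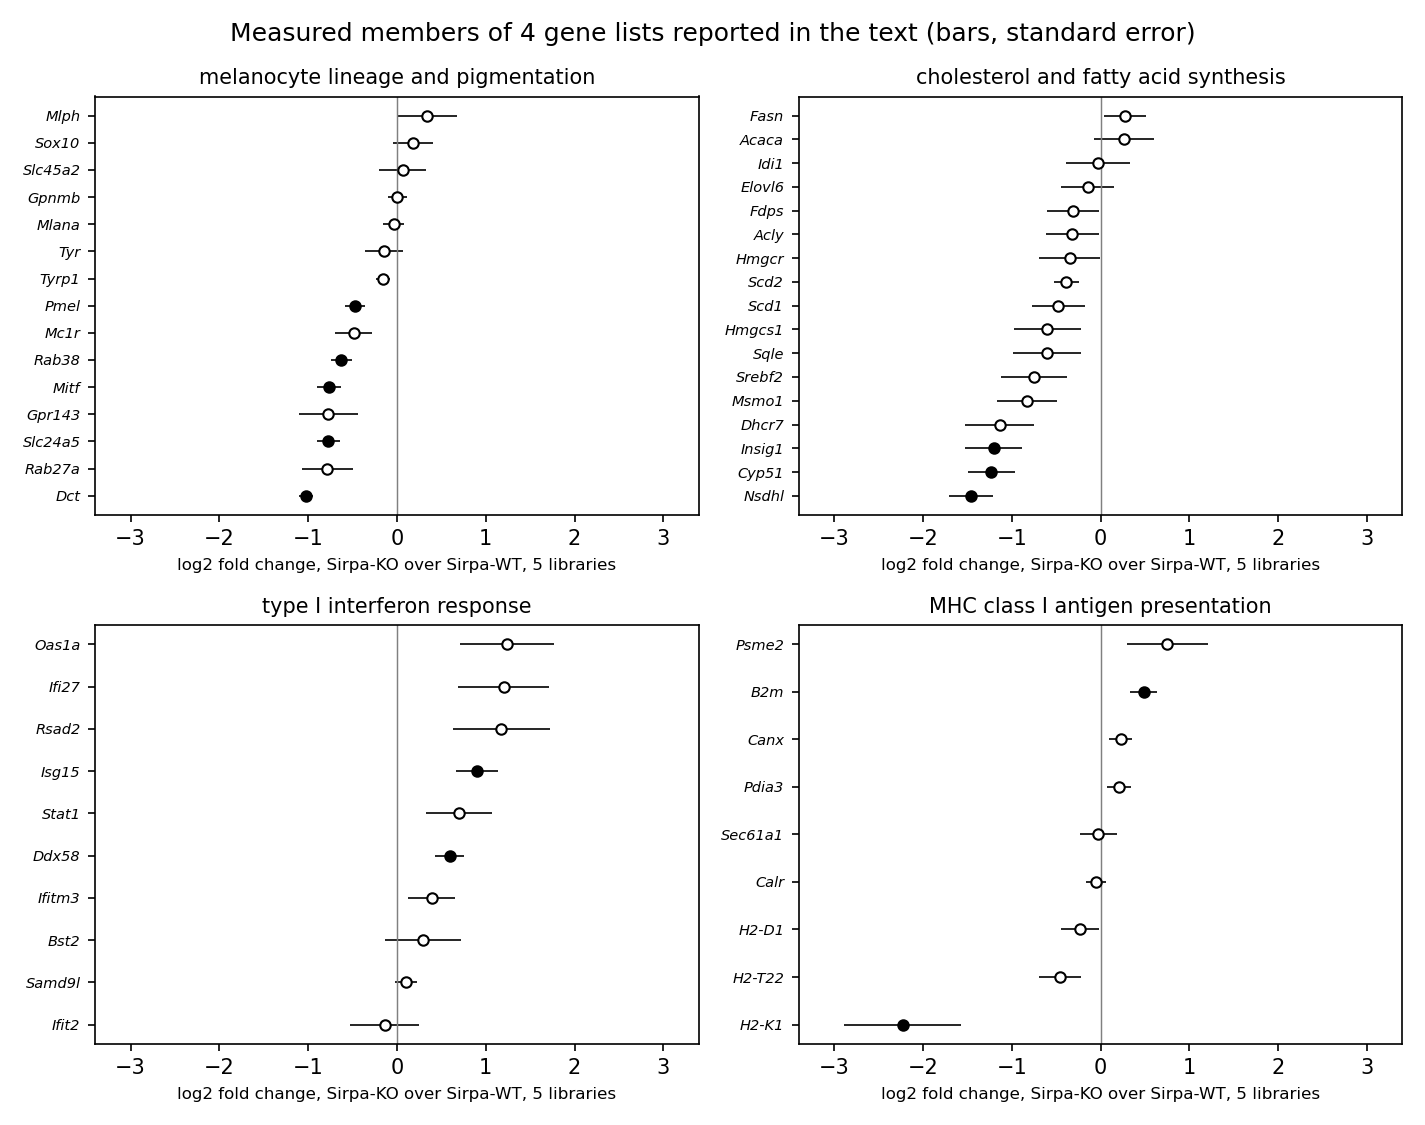
Log2 fold change of the members of 4 gene lists reported here, Sirpa-KO over Sirpa-WT without the deep library (x axis, log2 units; bars, standard error; filled points, adjusted p of at most 0.05 in edgeR). The 5 called melanocyte members and the 3 called sterol members drawn lie below 0, the 2 called type I interferon members above 0, and the antigen presentation list holds 1 called member on each side.

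Antigen presentation genes did not move together. Of 9 measured MHC class I genes, B2m, the invariant light chain, rose (0.48 ± 0.15, SE) and the heavy chain gene H2-K1 fell (-2.23 ± 0.66), with the same pair when adjusted over the list alone. H2-K1 was low, at 31.5 ± 15.1 CPM in Sirpa-WT (SD, n = 3) and 6.8 ± 9.6 in the shallow Sirpa-KO libraries (SD, n = 2), and shares 13.6% of its sequence words with pseudogenes. Its fall rests on 15, 5 and 15 counts against 0 and 5, and it was not called with DESeq2. Without Sirpa-KO replicate 2, which has the 0, it stood at -1.34 and was not called; without Sirpa-KO replicate 3 the fitted value of -6.56 is set by the prior count and gives no size. H2-D1 stood at -0.23 (edgeR adjusted p = 0.586), and at 0.051 with the trend removed. Neither B2m (0.34) nor H2-K1 (-2.06) passed with the trend removed. B2m was also not called with DESeq2, the replicate block, no filter, the filter at 1 CPM, protein-coding genes only or without Sirpa-WT replicate 1. Its log2 fold change fell as low as 0.23 over the alternatives. In the SIRPα-CD47 signalling list, 0 of 5 measured genes passed edgeR's test, and 1 passed, higher, when adjusted over the list alone. Ptpn11, the phosphatase SHP-2 that binds SIRPα, had a log2 fold change of 0.66 ± 0.23 (SE, edgeR adjusted p = 0.0522), and Cd47 of -0.24 ± 0.39 (adjusted p = 0.788). Ptpn6 and Cd274, the genes of SHP-1 and PD-L1, stood at or below 12.1 CPM and 5.44 CPM in each shallow library, under the count filter.

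Among the largest changes without the deep library, 12 genes each way were named by the rule, of which Cxcl10 and Tspan10 alone were called under each alternative that tested them. The rises ran from Bpgm (1.70), a red-cell glycolytic enzyme gene, and Hmmr (1.37), a spindle-associated hyaluronan receptor gene, to Fam198b (1.05). Most rest on few counts: all but Cxcl10 and Fam198b had at most 31 counts in each shallow library. Bpgm had 5, 7 and 1 counts in Sirpa-WT against 15 and 15 in the shallow Sirpa-KO libraries, and Zfp451 8, 6 and 6 against 19 and 17. Cxcl10, Nup35 (1.20), Arid1a (1.16) and Fam198b were still called with the trend removed, and the other 8 were not, although their fold changes stayed large (Bpgm 1.48, Hmmr 1.17, Zfp451 1.14). Nup35 and Arid1a deviated downward in the deep library, judged against its upward shift, so keeping the call adds little for them. DESeq2 called neither Nup35 nor Arid1a. Nup35 was also not called with the replicate block, no filter, the filter at 1 CPM, or without Sirpa-WT replicate 1 or 3. The falls ran from H2-K1, the axon-guidance gene Sema6d (-1.94), the CD81-binding Igsf8 (-1.86) and the thyroid hormone receptor gene Thra (-1.75) to the melanocyte-enriched tetraspanin gene Tspan10 (-1.41). In Sirpa-KO replicates 2 and 3, Thra had 2 and 8 counts, Igsf8 3 and 8, and Sema6d 5 and 5. Other falls were as thin there, with Hpse at 7 and 5 counts, Nsmce1 6 and 4, Gna12 9 and 7, and Flot1 5 and 5. Over the alternatives Thra ran from -2.97 to -1.16 and Igsf8 from -2.66 to -1.41, and DESeq2 called neither. Tspan10 went from 475 ± 5.6 CPM (SD, n = 3) to 192 ± 50.9 (SD, n = 2), and stood at 112 in the deep library. Heparanase (Hpse, -1.65), Gna12 (-1.51), the glutathione transferase gene Gsta2 (-1.55) and Nsmce1 (-1.62) fell too, the last 2 with 8.97% and 10.7% of sequence words shared with pseudogenes. With the trend removed, 8 of the 12 falls were still called, and H2-K1 (-2.06), Thra (-1.47), Flot1 (-1.28) and Nrm (-1.15) were not, at these log2 fold changes. Some genes named in this report lie near each other and moved the same way, so they may not be separate results. H2-K1, Flot1 and Nrm start at 33996017, 35823230 and 35861318 of chromosome 17. Hmmr and the p53 target Ccng1 are close on chromosome 11, Naa25 and Ptpn11 on chromosome 5, and Sema6d and Slc24a5 on chromosome 2.

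**Figure D3:**
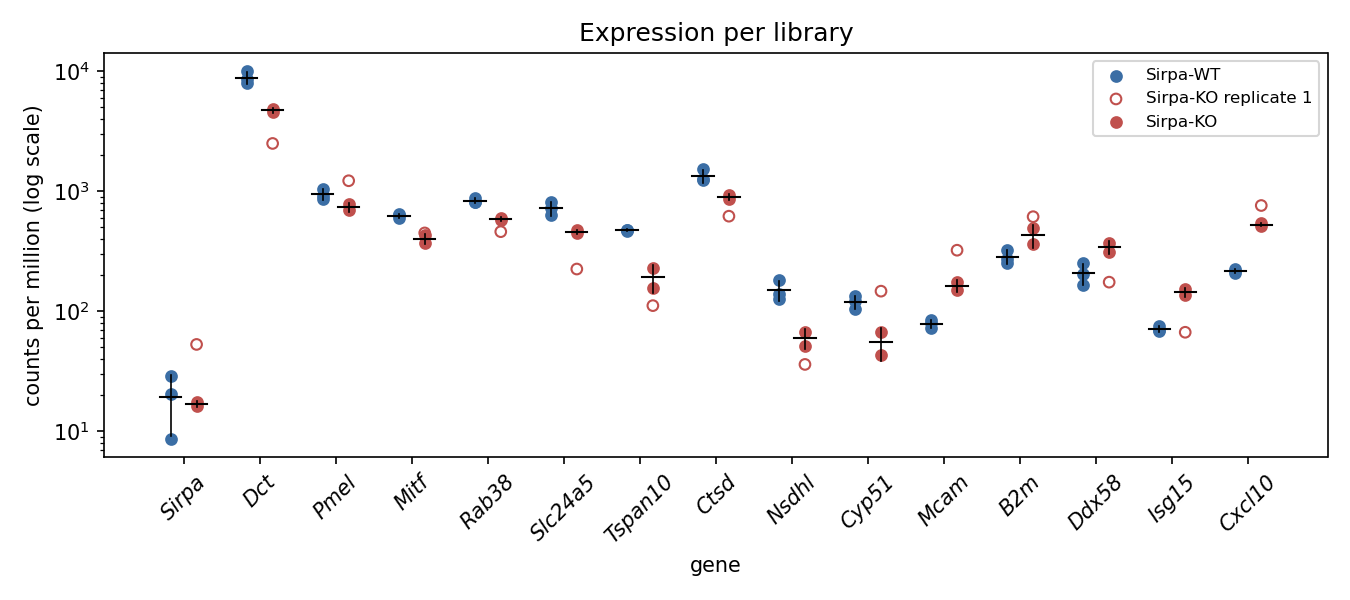
CPM of 15 genes in each library (log axis; blue, Sirpa-WT; filled red, the 2 shallow Sirpa-KO libraries; open red, the deep library; black, mean and SD of the shallow libraries of each group). Cxcl10 lies at 206 to 226 CPM in Sirpa-WT and at 516 to 760 in the libraries labelled Sirpa-KO, and Dct at 7901 to 9935 and 2496 to 4863.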

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

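The alternatives on gene type, gene length, thinning and the trend on the ratio to Sirpa-KO replicate 1, and all alternatives of the 5-library fit, were chosen after seeing the data. The count of 0 genes over 6 libraries (edgeR; 344 at an unadjusted p under 0.05) stayed 0 under the other scalings, filters, gene types, thinning, length correction, robust=FALSE and the replicate block, and was 1 with DESeq2 and 1283 with limma voom. Leaving out each library gave 0 to 322, the latter without Sirpa-KO replicate 1. The number of genes changed more than 2-fold was 0 in edgeR, 1 with DESeq2, 1245 with limma voom and 0 to 60 with each library left out. The cause of these differences between tools was not tested. Depth limits the shallow libraries to genes above about 28.0 CPM.

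The Sirpa log2 fold change of 0.17 ranged from -0.38 to 0.57 with each library left out. It was -0.011 in protein-coding genes, -0.024 in those without pseudogene sequence, -0.21 with the length trend removed and -0.012 with Sirpa-KO replicate 1 thinned. Camera called 1 list over 6 libraries, 2 with RLE, 2 with library size alone, 7 with no filter, 4 with at least 1 CPM in 3 libraries, 3 with the replicate block, 2 in protein-coding genes, 2 in those without pseudogene sequence and 0 with an estimated correlation. Leaving out each library gave 2 to 4.

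Without Sirpa-KO replicate 1, the 322 calls (73 higher, 249 lower) became 132 with DESeq2 (16 and 116), 109 with the trend removed (41 and 68), 200 in protein-coding genes (150 lower) and 157 in those without pseudogene sequence (39 and 118), where fewer genes were tested. Library size alone gave 279 higher and 128 lower, no filter 38 higher and the filter at 1 CPM 48 higher. The replicate block gave 316 calls, 249 of them among the 322. It no longer called 13 named genes: Bpgm, Zfp451, Cdk12, Nup35, Gpx1, Bub1, B2m, Gapdh, Mfge8, Mcoln1, Nrm, Nsmce1 and H2-K1. Leaving out a further library gave 125 to 351 calls, 15 to 99 higher and 102 to 252 lower. The lowest came without Sirpa-KO replicate 2 (125; 15 higher, 110 lower), without Sirpa-KO replicate 3 (127; 25 higher, 102 lower) and without Sirpa-WT replicate 2 (214; 46 higher). Where Sirpa-KO replicate 2 or 3 is left out, the lone Sirpa-KO library is assumed to vary like the Sirpa-WT ones. The 2-fold count of 60 was 97 with library size alone, 9 with DESeq2, 24 with the trend removed and 0 with glmTreat, and 28 to 75 with a library left out (28 and 39 without Sirpa-KO replicates 2 and 3). The 4 called lists became 0 with an estimated correlation and 7 with the trend removed, none of which held with an estimated correlation (lowest adjusted p = 0.132 over the lists tested). The cause was not tested.

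Of 49 named genes called in this fit, 9 stayed called with their direction under each alternative that tested them: Cxcl10, Rab38, Ctsd, Mitf, Slc24a5, Ndufa2, Dct and Tspan10 under 18, and mt-Co1 under 17, since the genes without pseudogene sequence leave it out. Named genes that changed sign in the 5-library fit were not called there. With the trend removed Lgals1 was -0.037, Vim -0.16 and H2-D1 0.051. With a further library left out, Cd47 ran from -0.67 to 0.089, Ddx3y from -0.66 to 0.56 and Vim from -0.12 to 0.19. Over 6 libraries, where none was called by edgeR, library size alone gave Sparc 0.12, Gapdh 0.18 and Pmel 0.035, and the length correction gave Ndufa2 2.43 and Nsmce1 0.61. Mif was -0.013 with RLE, -0.075 with no filter, -0.14 with the filter at 1 CPM, -0.022 with the replicate block, -0.12 in protein-coding genes and -0.062 thinned. Leaving out each library took Mif from -0.56 to 0.40, Sparc from -0.45 to 0.25 and Tyr from -0.15 to 1.31.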

Other observations

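The tests of counting noise, of another cell type, of splits with the trend removed, of position on the chromosomes and of a shared preparation or clone were chosen after the result was seen. Without Sirpa-KO replicate 1, the deep library, genes of further lists also changed in edgeR's test. Of 18 measured lysosome genes, 3 fell, with 3 adjusted over the list alone: the protease gene Ctsd (-0.70), Mfge8 (-0.83), which encodes a bridging protein for the uptake of dying cells, and the channel gene Mcoln1 (-1.17). Of 19 genes of the unfolded protein and integrated stress response, 1 fell, also adjusted over the list alone: Xbp1 (-0.87), a transcription factor of that response. Camera called this list lower (adjusted p = 0.0459), and adjusted p = 0.371 with an estimated correlation. Of 14 glycolysis and hypoxia genes, Gapdh (-0.28) and Bnip3 (-0.70) fell, and 3 fell adjusted over the list alone; both share sequence words with pseudogenes (28.0% and 21.4%). Of 30 nuclear-encoded oxidative phosphorylation genes, Ndufa2 (-0.81) fell, with 1 higher and 1 lower adjusted over the list alone. Over 6 libraries camera called that list higher (adjusted p = 0.00122), and adjusted p = 0.643 with an estimated correlation. Of 10 mitochondrially encoded genes, mt-Co1 fell (-0.51), with the same 1 adjusted over the list alone, and 69.7% of its words are shared with pseudogenes. Of 5 MAPK output genes, the ERK phosphatase gene Dusp6 fell (-0.57), with 1 adjusted over the list alone. Ctsd, Xbp1, Gapdh, Ndufa2 and mt-Co1 were still called with the trend on the ratio to the deep library removed; Mfge8 (-0.60), Mcoln1 (-0.89), Bnip3 (-0.48) and Dusp6 (-0.32) were not, at these log2 fold changes.

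Rises in other lists were fewer. Of 10 p53 targets, Mdm2 (0.90) and Ccng1 (0.57) rose, with 2 higher and 1 lower adjusted over the list alone. Of 8 integrin and adhesion genes, Mcam (0.92) and Itga4 (1.04) rose, with 3 higher and 1 lower adjusted over the list alone. Of 27 cell cycle genes, the spindle checkpoint gene Bub1 (0.65) rose, and 0 passed adjusted over the list alone. None of these 5 was called with the trend removed, at 0.69 for Mdm2, 0.35 for Ccng1, 0.70 for Mcam, 0.83 for Itga4 and 0.43 for Bub1. Markers of other cell types were low. Summed CPM in any library reached 32.6 for myeloid, 9.72 for lymphocyte, 70.5 for fibroblast, 4.86 for keratinocyte, 0.301 for erythroid and 199 for endothelial markers, the last mostly Eng (116 to 197). Y-linked genes and Xist summed to 23.6 to 49.0 CPM in the shallow libraries and 0.971 in the deep library. The Y-linked gene Ddx3y had 7 to 18 counts in each shallow library and 0 in the deep library.

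The deep library differed from the 5 others in pseudogene share and in which stretches of the chromosomes were low. Counting noise is argued against, since the 2 shallow Sirpa-KO libraries correlated across genes at r = 0.944. Cells of another type stay open: the summed melanocyte CPM in the deep library was 1.32 times the lowest of the others, where a smaller share of other cells would not show. The summed dedifferentiated or mesenchymal melanoma genes reached 2962 CPM there and at most 718 in the others. That sum was mostly Vim, at 2156 CPM in the deep library and 318 to 451 in the others. Alignment that did not cross exon junctions in the shallow libraries stays open, because the median log2 ratio was higher in the genes with the shortest exons than in those with the longest by 0.14, with a bootstrap interval of 0.058 to 0.20 that reaches the bound set for excluding it. A file that came from another sample was not tested and stays open, with no Ddx3y count in the deep library. A biological explanation was not tested either, as the design gives none for a single library.

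For the 322 genes called without the deep library, 91.3% of calls lay on chromosomes with a median log2 fold change within 0.2 of the overall one. That share decides little, as only chromosome 17 lay outside and the rest hold most tested genes. The medians within 0.2 argue against copy number along those whole chromosomes, but not along parts of them. Chromosome 17 lay at -0.24, with 28 of its 270 tested genes called and 2 of these higher, so copy number there stays open. The values argue against gene length (385 calls with its trend removed) and against blood or immune cells (at most 35.4 CPM). Over the called genes together they also argue against reads mixed in from a library like the deep one (0.213 of the observed change predicted, interval 0.188 to 0.232). By direction the value was 0.196 for genes called lower and 0.252 for those called higher. The latter lies just past the bound set in advance, so mixed reads stay open for the rises. For the 83 genes still called once the trend on the ratio to the deep library was removed, that average trend is argued against as the whole cause. Position itself was not modelled, so a local shift larger than the trend stays open for them. Neighbouring genes correlated in fold change at 0.134 before and still at 0.0422 after (permutation p = 0.048, 1-sided). For the 239 others a component of the counts that follows chromosome position may contribute and cannot be told apart from the group difference. Their median absolute log2 fold change went from 0.60 to 0.36 (median ratio 0.615). The 10 splits of 5 libraries are too few for a share under 0.05; the real split called 322 genes and the highest other 6 (1 of 10 as large), or 109 and 17 with the trend removed (1 of 10 as large). The 6 libraries also have 10 splits, too few for such a share, and the real split and all others called 0 (10 of 10 as large; edgeR, 344 genes at an unadjusted p under 0.05, DESeq2 1, limma voom 1283).

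Genes called without the deep library deviated the same way in it in 145 of 156 cases (92.9%), against 2335 of 3305 uncalled genes (70.7%), taking protein-coding genes without pseudogene sequence. Deviation is judged against the upward shift of the deep library. A gene can thus count as lower there with CPM above each Sirpa-WT library, as Pmel, Cyp51 and Insig1 did. Mixed reads are argued against (0.149 of the change predicted). The component that follows chromosome position stays open. A gene's fold change correlated across genes with the mean deviation of its adjacent genes (Spearman rho 0.243, highest of the permutations 0.0834, 1-sided p = 0.001, the smallest they can give). Given these neighbours, the correlation with its own deviation went from 0.517 to 0.473. That correlation was 0.182 within the low-ratio genes and 0.203 within the others, so part of it lies between these sets. A preparation or cell clone shared by the libraries labelled Sirpa-KO cannot be told apart from the genotype, because the design joins them: the correlation for the real split was 0.510 and those of the other splits ran from -0.42 to 0.172. An effect of Sirpa loss stays open as a hypothesis that these libraries do not test apart from the line they came from.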
